A study of Mus musculus with 8 samples.

How the data were processed

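RNA was sequenced in bulk from the carotid bifurcations, the forks of the carotid arteries that hold the oxygen-sensing carotid bodies together with surrounding tissue, taken from both sides of male mice at postnatal day 42 in the dark phase of the day. Per the labels, 4 samples carried an Mecp2 knockout and 4 were wild-type littermates. RNA was extracted with TRIzol and libraries were made with a strand-preserving mRNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The labels do not say whether each sample came from a separate animal, so the p-values measure the spread between these samples.

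The deposited values are raw counts of reads per gene symbol, made by the authors with Trimmomatic 0.38, HISAT2 2.2.1 and HTSeq 0.13.5 on the mouse build GRCm39, per the submitters' processing notes. The gene annotation and the strand setting of the counting were not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Each file ended in 5 HTSeq summary rows that name no gene, and these stayed out of library sizes and tests. Non-uniquely aligned reads in those rows took 11.9 to 15.6% of reads in wild-type and 16.3 to 20.8% in knockout libraries. Reads with no feature took 3.11 to 4.93%, ambiguous reads 4.03 to 9.30%, low-quality alignments 0.401 to 0.622% and unaligned reads 0.228 to 0.709%. Gene counts summed to between 27434761 and 42325608 per library, so a gene at 1 CPM (a count scaled to a library of 1e+06 gene counts) rests on 27.4 to 42.3 counts before scaling. The common biological coefficient of variation was 0.318.

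Analysis used R 4.3.3. Genes were kept by the filterByExpr rule of edgeR 4.0.16, which left 17209 of 41079 genes, and libraries were scaled by TMM. The knockout was compared with the wild type by edgeR's quasi-likelihood F test with robust dispersion estimates and Benjamini-Hochberg adjustment over the tested genes, at an adjusted p threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F value. CPM values use the TMM-scaled library sizes, and log2 CPM values for scores use a prior count of 2. A list's score in a library is the mean log2 CPM of its tested members.

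The 42 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, beside camera with the correlation estimated per list and fry, each adjusted over the 42 lists. Named genes were Mecp2, the 10 higher and 10 lower genes with the largest fold change among those past the threshold with a mean log2 CPM of at least 0 and no overlap between groups, the 5 higher and 5 lower genes with the smallest p, up to 4 passing members of each list, 14 genes of prior interest, and up to 2 members of each list with no passing member. Genes outside the rule are said to have been chosen after their values were seen. Mitochondrially encoded genes carried other symbols in the files and all 13 were matched through Entrez identifiers. Per-library measures and scores were compared by exact two-sided permutation tests over the 70 assignments of 4 and 4 libraries, for which the smallest possible p is 0.0286. The gene length measure was the mean log2 CPM of protein-coding genes spanning over 100 kb minus that of shorter ones. Gene spans and the order of genes beside Mecp2 came from an annotation of GRCm38, not the authors' build, so no coordinates are given, and 91.2% of tested genes matched it by symbol.

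The alternatives were other scalings, other filters, leaving out each library in turn, the replicate number as a block, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0, limma-voom with quality weights, other thresholds and other list tests. After the data were seen, fits without the 4 libraries with the highest salivary gland score, with the salivary or the general adipocyte score in the model, and without the mitochondrially encoded genes were added. The 8 general adipocyte markers are all members of the adipocyte list. No library was left out of the reported comparison, and no 2 libraries of a group agreed within sampling noise. The edgeR step was tested on simulated counts for the 17209 genes of this comparison, with 200 genes changed. It recovered 10% of genes changed 1.5-fold, 40% of those changed 2-fold, 82% of those changed 4-fold and 80% of those changed 8-fold. Of its calls, 12 were false, 10.2% of the total, and it made 0 calls when no gene was changed. A list lowered 1.5-fold, that of synaptic vesicle release genes, was recovered by all 3 list tests. Simulated genes varied independently, while in the data this list had an estimated correlation of 0.631. The simulation therefore does not show what the list tests recover in these data. Figures were drawn with matplotlib.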

Results

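The data are gene counts from bilateral carotid bifurcations of male mice at postnatal day 42, in 8 libraries, 4 from Mecp2 knockout and 4 from wild-type littermate samples. Mecp2 lies on the X chromosome and encodes a protein that binds methylated DNA, and its loss causes Rett syndrome, in which breathing is disturbed. The series addresses whether the carotid body, the organ that senses arterial oxygen, is affected. Gene counts summed to 42325608, 29159046, 27434761 and 32856126 in wild type replicates 1 to 4 and to 31113465, 31778083, 40124515 and 41345004 in knockout replicates 1 to 4. The dissected piece held more than carotid body, so markers of other tissues are given with the comparison.

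Mecp2 itself was 15.8-fold lower in the knockout. Its level was 69.6 ± 4.97 CPM (SD, n = 4) in the wild type and 4.38 ± 2.75 CPM in the knockout, a log2 fold change of -3.98 (SE 0.44, edgeR adjusted p = 0.00704). The 4 knockout libraries held 92, 136, 57 and 335 Mecp2 counts, which is 4.48, 6.58, 2.46 and 11.7% of the wild-type mean. The call held in each of the 8 fits that left out a library. It missed the threshold without the 4 libraries highest in salivary gland transcripts (adjusted p = 0.0502) and with an adipocyte marker score in the model (adjusted p = 0.0802), with log2 fold changes of -3.69 and -3.65. Irak1, the neighbour of Mecp2 on the chromosome, had a log2 fold change of -0.05 (SE 0.11, adjusted p = 0.821). Of the 40 tested genes nearest to Mecp2 in gene order, 20 on each side, 6 passed the threshold, where 8.29% of all tested genes did.

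Across the 17209 genes tested, 1427 passed an adjusted p of 0.05 in edgeR, 969 higher and 458 lower in the knockout. A change of at least 1 log2 unit was reached by 322 of the higher and 112 of the lower genes. The genotypes did not overlap in 1389 of the 1427 genes, and in 17.2% of all tested genes, where chance gives 2.86%. The higher genes with the smallest p were Slit1, an axon guidance ligand (log2 fold change 2.83, SE 0.24), Sstr2, a somatostatin receptor (2.67, SE 0.21), Me1, the cytosolic malic enzyme that supplies NADPH (1.55, SE 0.13), Tnr, an extracellular matrix glycoprotein (2.08, SE 0.18), and Gja1, the gap junction protein connexin 43 (1.41, SE 0.12). The lower genes with the smallest p were Serpinb2, an inhibitor of plasminogen activators (-3.31, SE 0.23), Cpne9, a calcium-binding copine (-2.09, SE 0.15), Chrm1, a muscarinic acetylcholine receptor (-1.16, SE 0.11), Kcng4, a potassium channel subunit (-1.72, SE 0.17), and Cfd, the adipose-derived complement factor D (-2.26, SE 0.23). Adjusted p values of these 10 genes ran from 0.000911 to 0.00248, and each held in all 8 fits that left out a library.

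Among genes with a mean log2 CPM of at least 0 and no overlap between genotypes, the largest rises were those of Atp4b, a gastric proton pump subunit, and Elovl3, a fatty acid elongase. Atp4b was at 0.0216 ± 0.0432 CPM in the wild type, with counts in 1 of 4 libraries, and at 2.04 ± 0.747 CPM in the knockout. Elovl3 went from 4.37 ± 5.39 to 144 ± 59.7 CPM (log2 fold change 5.02, SE 1.02, adjusted p = 0.0338). It passed in 1 of the 8 fits that left out a library (log2 fold change 4.605 to 6.368, edgeR adjusted p up to 0.110). Other large rises were those of Gm15241 (3.68), Mtarc1 (3.48), Slc15a5 (3.45), Gm51680 (3.27), Acot12 (3.26), Chrna2, a nicotinic receptor subunit (3.16), and Adcy10, the soluble adenylyl cyclase (2.96), all from wild-type levels under 1 CPM. Beside Mecp2, Serpinb2, Cfd and Cpne9, the largest falls were those of Mc3r, a melanocortin receptor (-3.96), Anxa8, an annexin (-3.11), Omp, the olfactory marker protein (-2.30), Gm36860 (-2.26), Ifi27l2a, an interferon-induced gene (-2.18), and C7, a complement component (-2.06). Omp went from 144 ± 58.9 to 29.1 ± 4.05 CPM.

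The number of calls rested on which libraries were used. It was 262 without wild type replicate 2, 97 without wild type replicate 3, and 632, 654, 665 and 721 without knockout replicates 1 to 4, 154 without the 4 libraries highest in salivary transcripts, 3 with the adipocyte score in the model, 2590 with DESeq2 and 2611 with limma-voom. Of the 93 named genes past the threshold, 84, 36, 27 and 74 stayed past it without wild type replicates 1 to 4 and 56, 56, 54 and 60 without knockout replicates 1 to 4. The 27 that did so in all 8 fits were Mecp2, Atp4b, Gm15241, Mtarc1, Slit1, Mc3r, Serpinb2, Anxa8, Omp, Cfd, Ifi27l2a, Cpne9, C7, Sstr2, Me1, Tnr, Gja1, Chrm1, Kcng4, Chgb, Slc5a5, Egln1, Pdk1, Syt7, Elovl6, Plin2 and Bst2. Without wild type replicate 4, 732 genes were higher and 807 lower.

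**Figure D1:**
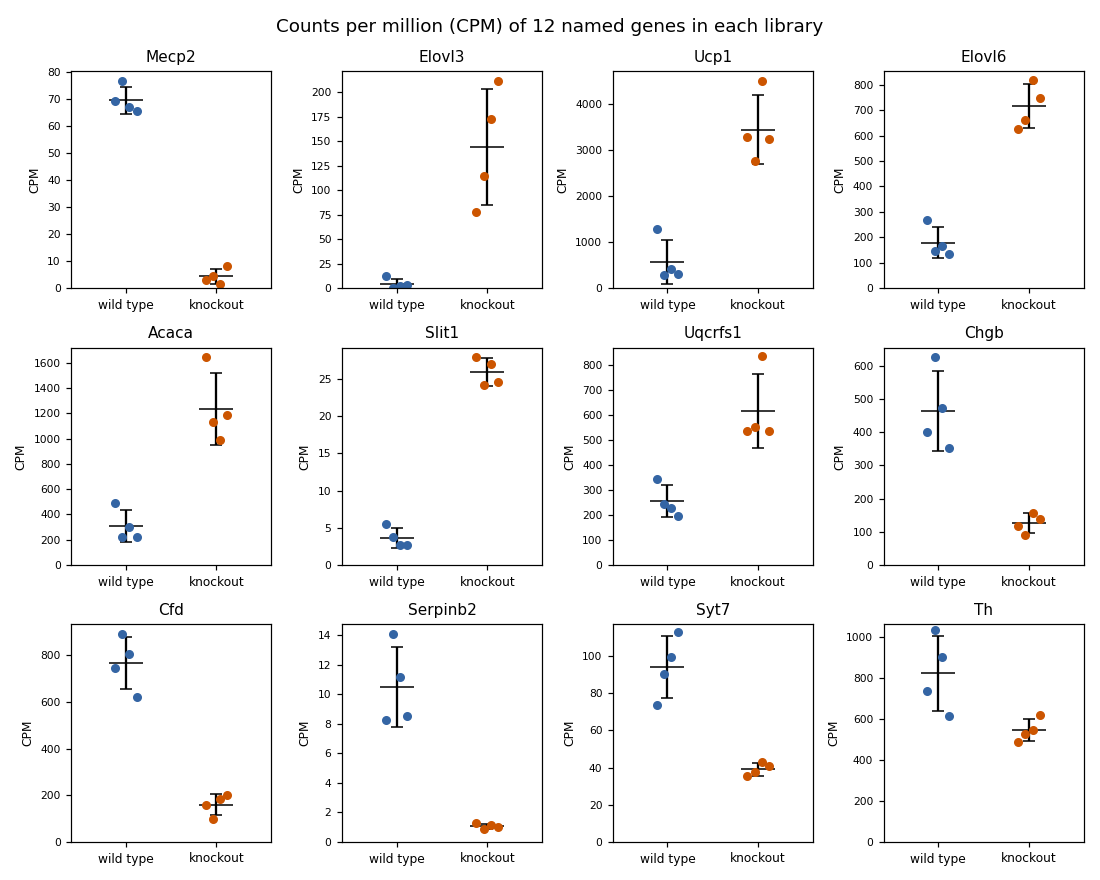
Levels in CPM (linear axis from 0) of 12 named genes in the 4 wild-type (blue) and 4 knockout (orange) libraries; points are libraries, long bars means and whiskers the SD. Mecp2 averaged 69.6 CPM in the wild type and 4.38 CPM in the knockout, and groups do not overlap for any gene shown except Th, whose adjusted p was 0.0762.

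Genes of fatty acid synthesis and storage were higher in the knockout. Of 21 tested members, 14 rose, 0 fell and 7 did not pass, and 17 rose when adjusted over the list alone. Elovl6, which elongates palmitate, went from 179 ± 61.3 to 715 ± 86.8 CPM (log2 fold change 2.00, SE 0.23, edgeR adjusted p = 0.00442). Acaca, the rate-limiting acetyl-CoA carboxylase, had a log2 fold change of 2.00 (SE 0.29), Plin2, a lipid droplet coat protein, 1.68 (SE 0.23), and Me1 1.55. The list's median log2 fold change was 1.08 (camera adjusted p = 7.22e-22, adjusted p = 0.386 with an estimated correlation, fry adjusted p = 0.0172). Adipocyte markers moved apart. Ucp1, the uncoupling protein of brown fat, went from 571 ± 482 to 3449 ± 744 CPM (log2 fold change 2.59, SE 0.51, adjusted p = 0.0209), and Elovl3 and Fabp4 also rose, the last chosen after its value was seen. Ucp1 passed in 5 of the 8 fits that left out a library (log2 fold change 2.331 to 3.358, edgeR adjusted p up to 0.0887). Cfd fell from 767 ± 113 to 160 ± 45.1 CPM, and Retn, the hormone resistin, had a log2 fold change of -1.04 (SE 0.22). In all, 3 of 14 adipocyte markers rose and 2 fell, or 7 and 2 adjusted over the list alone, with a camera adjusted p of 0.0509. The 8 of these 14 that mark adipocytes in general, a subset chosen after the data were seen, also had a median log2 fold change of 0.57. With the score of these 8 in the model, the median of the fatty acid list was 0.63, and the calls of Elovl6, Acaca and Me1 were lost (adjusted p = 0.0727, 0.148 and 0.0716), at log2 fold changes of 1.54 (SE 0.23), 1.49 (SE 0.32) and 1.39 (SE 0.17). Cholesterol synthesis genes had 1 of 24 members past the threshold, Ebp, which fell (-0.54, SE 0.13), and 0 adjusted over the list alone (list adjusted p = 0.255).

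Nuclear genes of mitochondrial respiration were higher in the knockout. Of 39 nuclear genes of oxidative phosphorylation, 31 rose and 0 fell, and 38 rose when adjusted over the list alone. Examples were Uqcrfs1, the Rieske protein of complex III (log2 fold change 1.28, SE 0.22), Uqcrc2 (1.05, SE 0.19), and Ndufs4 (1.00, SE 0.19) and Ndufs1 (0.96, SE 0.18) of complex I. The list median was 0.92 (camera adjusted p = 5.61e-26, adjusted p = 0.480 with an estimated correlation, fry adjusted p = 0.0458). With the score of the 8 general adipocyte markers in the model this median was 0.44, and the rise of the list above those markers overlapped between genotypes (exact two-sided permutation p = 0.143). Among 13 genes encoded by mitochondrial DNA, 4 rose and 0 fell, namely ND6 (1.40), ND5 (1.37), ND1 (1.203) and ND2 (1.09), and 11 rose adjusted over the list alone (camera adjusted p = 7.56e-08, adjusted p = 0.480 with an estimated correlation). Of the 8 fits that left out a library, ND6 and ND5 each passed in 6, and ND1 and ND2 each in 1. These 13 genes took 12.02 ± 3.35% of counts in the wild type and 19.8 ± 2.54% in the knockout (exact two-sided permutation p = 0.0286, adjusted over 8 library measures p = 0.0762). The nearest libraries were wild type replicate 1 at 16.6% and knockout replicate 4 at 16.7%, and the centred score of these genes overlapped between genotypes, at -0.031 and -0.207 log2 units in the same libraries. ATP6 and ATP8 overlap, so their counts are uncertain.

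Hypoxia-inducible factor targets also rose in part. Of 21 members, 6 rose and 0 fell over all genes, while adjusted over the list alone 10 rose and 3 fell (camera adjusted p = 0.00472, adjusted p = 0.386 with an estimated correlation, fry adjusted p = 0.00327). The glycolytic enzymes Eno1 (log2 fold change 1.21, SE 0.21) and Ldha (0.91, SE 0.16), the pyruvate dehydrogenase kinase Pdk1 (1.14, SE 0.15) and the prolyl hydroxylase Egln3 (1.05, SE 0.18) were among them. Median log2 fold changes of general adipocyte markers (0.57) and skeletal muscle markers (0.93) were also above 0. No per-library comparison of the target list with those markers was made. Of 21 oxygen-sensing and factor components, 3 rose and 1 fell, or 6 and 2 adjusted over the list alone (list adjusted p = 0.0608). Those that rose were Egln1, another prolyl hydroxylase (0.97, SE 0.12), Egln3 and Ndufa4 (0.98, SE 0.24), and Or51e2, an olfactory receptor (-0.54, SE 0.14), fell. Epas1, which encodes HIF2-alpha, had a log2 fold change of 0.65 (SE 0.18, adjusted p = 0.0542) and Cox4i2 0.48 (SE 0.21, adjusted p = 0.190). Higd1c, a glomus cell gene, had 1 count in 1 library and 0 in the others, which was too low to test.

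Among markers of glomus cells, the oxygen-sensing cells of the carotid body, 3 of 22 fell and 0 rose, or 7 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0509). Chgb, which encodes the secretory granule protein chromogranin B, went from 463 ± 120 to 126 ± 29.3 CPM (log2 fold change -1.88, SE 0.23, adjusted p = 0.00603), and Rgs4, a regulator of G protein signalling, had a log2 fold change of -0.75 (SE 0.14). Th, the rate-limiting enzyme of catecholamine synthesis, was at 821 ± 185 and 544 ± 54.6 CPM (log2 fold change -0.59, SE 0.18, adjusted p = 0.0762). Chga had a log2 fold change of -0.14 (adjusted p = 0.725), Dbh -0.38 (0.252), Drd2 -0.29 (0.407), and the potassium channels Kcnk3 1.13 (0.0565) and Kcnk9 0.41 (0.438). Cox4i2, another glomus cell marker, averaged 2.24 CPM in the wild type and 3.13 CPM in the knockout. Dbh, from the sympathetic neuron list, averaged 2040 and 1568 CPM. Which cells held the Chgb, Rgs4 and Th transcripts was not measured. Synaptic vesicle release genes had 3 of 28 members that fell and 0 that rose, or 7 that fell adjusted over the list alone. These were Syt7, a calcium sensor (-1.26, SE 0.14, adjusted p = 0.00372), Sv2c (-0.94, SE 0.19) and Stx1a (-0.60, SE 0.14). The list median was -0.46 (camera adjusted p = 5.12e-07, adjusted p = 0.727 with an estimated correlation, fry adjusted p = 0.185). No sympathetic neuron marker of 15 passed (camera adjusted p = 0.0293, adjusted p = 0.727 with an estimated correlation), with Chrnb4 at -0.44 (adjusted p = 0.102) and Ntrk1 at -0.55 (adjusted p = 0.138), and the median was -0.28. Of 14 sensory ganglion markers, only Nefm passed and fell (-1.14, SE 0.27), with 2 lower adjusted over the list alone (list adjusted p = 0.145). P2rx3 and P2rx2, purine receptors of the petrosal afferents, had log2 fold changes of 0.21 and 0.50 (adjusted p = 0.930 and 0.675), with 50.3 and 25.3 CPM in wild type replicate 1 and at most 6.27 and 6.74 CPM in the other wild-type libraries.

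Transmitter, receptor and channel lists held 1 to 4 changed genes each, and no such list passed camera. Counts adjusted over the list alone are given where they differ from those over all genes. In the catecholamine list Comt rose (0.73, SE 0.14), alone of 21 members, with 3 higher and 4 lower adjusted over the list alone (adjusted p = 0.519). Of 12 cholinergic genes, Slc18a3 (1.83, at 0.301 and 1.07 CPM) and Bche (0.53) rose and Chrm1 and Chrm2 (-0.60) fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.210). Adk rose (0.54) and Entpd2 fell (-0.74) among 21 purinergic genes, Slc6a4 rose (0.83) and Htr3b fell (-1.05) among 16 serotonin and GABA genes, and Agtr1a rose (0.64) and Npr1 fell (-0.84) among 24 vasoactive peptide genes, with list adjusted p of 0.436, 0.436 and 0.635; adjusted over the list alone, 2 serotonin and GABA genes fell. Among 31 potassium channels, Kcnc1 (0.82) and the pericyte channel Kcnj8 (0.97) rose and Kcnd1 (-0.99) and Kcnn3 (-0.69) fell, or 4 and 4 adjusted over the list alone (adjusted p = 0.356). Among 26 calcium and sodium channels, Scn8a (-0.73) and Cacnb3 (-0.63) fell, or 3 adjusted over the list alone (adjusted p = 0.219). Gfra3 (-1.04) and Lifr (-0.49) fell among 17 neurotrophic factor genes (adjusted p = 0.420), and Bdnf had a log2 fold change of 0.10 (adjusted p = 0.933). In the list of genes reported as MeCP2-regulated in brain, Nrxn3 (1.09), Uqcrc1 (0.93) and Id1 (0.53) rose and Gamt (-0.87) fell, out of 22 members, or 4 and 1 adjusted over the list alone (adjusted p = 0.436, median -0.01 with a mean of 0.11).

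Of 23 interferon-responsive genes, 4 fell, 0 rose and 19 did not pass, and 12 fell when adjusted over the list alone. Ifi27l2a fell most (182 ± 30.2 to 40.1 ± 13.8 CPM), followed by Bst2 (-0.83, SE 0.11), Stat2 (-0.56, SE 0.11) and Gbp3 (-0.43, SE 0.12) (camera adjusted p = 9.40e-08, adjusted p = 0.568 with an estimated correlation, fry adjusted p = 0.0729). Stat2 passed in 4 of the 8 fits that left out a library and Gbp3 in 0. Of 10 B cell markers, 4 rose, 0 fell and 6 did not pass, and 8 rose when adjusted over the list alone. The 4 were Cd22 (2.39), Ms4a1 (2.23), Cd19 (2.21) and Spib (1.93), at 0.440 to 0.836 CPM in the wild type and 2.38 to 3.67 CPM in the knockout (camera adjusted p = 4.37e-05, adjusted p = 0.568 with an estimated correlation, fry adjusted p = 0.0798). Centred B cell scores were 0.903 and 1.54 log2 units in knockout replicates 1 and 2, -0.0908 and 0.334 in knockout replicates 3 and 4, and at most -0.372 in the wild type. Knockout replicate 2 also had the highest neutrophil and mast cell (1.74), erythroid (1.46), cartilage and bone (2.43) and cell cycle (1.53) scores. Cd22 and Spib stayed past the threshold only without wild type replicate 1 (adjusted p up to 0.143 and 0.135 in the other 7 fits). Cd19 was lost without wild type replicates 2, 3 or 4 or knockout replicates 1 or 2 (up to 0.135), and Ms4a1 without wild type replicate 3 (0.067). Myelinating Schwann cell markers had 2 of 14 members that fell, Ugt8a (-0.60) and Mal (-0.51) (adjusted p = 0.000450, adjusted p = 0.727 with an estimated correlation), and glia markers 2 of 12, Apoe (-0.78) and Kcnj10 (-0.72), or 3 adjusted over the list alone (adjusted p = 0.0202, adjusted p = 0.480 with an estimated correlation). Ugt8a and Mal passed in 0 of the 8 fits that left out a library, Kcnj10 in 1 and Apoe in 3. Levels of Mal overlapped between genotypes. Gfap had a log2 fold change of -0.76 (adjusted p = 0.220). Of 15 smooth muscle and pericyte markers, Rgs5 (0.62, SE 0.11) and Kcnj8 rose (list adjusted p = 0.219), while Plvap (-0.67) fell among 14 endothelial markers (list adjusted p = 0.997, median 0.01 with a test pointing down). In the fits that left out a library, Rgs5 passed in 6 of 8, Kcnj8 in 3 and Plvap in 1. Cd14 (-1.03) fell among 14 macrophage markers (list adjusted p = 0.0608), and Cxcl14 (1.48) rose among 16 inflammatory genes (list adjusted p = 0.880, median -0.01, mean 0.11 and a test pointing down). T cell markers (Il7r 0.68, Trac -0.49), fibroblast markers (Fbln1 -0.79, Clec3b -0.70), extracellular matrix genes (Mmp2 -0.73, P4ha1 -0.73) and neutrophil and mast cell markers (Retnlg 3.44, Mmp8 3.35) had no passing member, with list adjusted p of 0.789, 0.186, 0.252 and 0.252; the matrix list had a median of -0.04, a mean of 0.03 and a test pointing down.

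Erythroid markers (adjusted p = 0.0337, adjusted p = 0.480 with an estimated correlation, fry adjusted p = 0.0456), with Hba-a1 at 0.76 and Hba-a2 at 0.90, and cell cycle genes (adjusted p = 0.0276, adjusted p = 0.727 with an estimated correlation), with Ube2c at 1.21 and Cdc20 at 1.15, had no passing member. Sdf2l1 (-2.02) fell alone among 20 heat shock and protein folding genes, with 0 adjusted over the list alone (list adjusted p = 0.0796). Circadian clock genes (Clock 0.33, Bmal1 0.53), glucocorticoid-responsive genes (Mt1 0.76, Pdk4 1.31) and immediate early genes (Atf3 0.87, Egr3 1.12) had no passing member, with list adjusted p of 0.436, 0.0608 and 0.802, though 2 glucocorticoid-responsive genes were higher adjusted over the list alone.

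**Figure D2:**
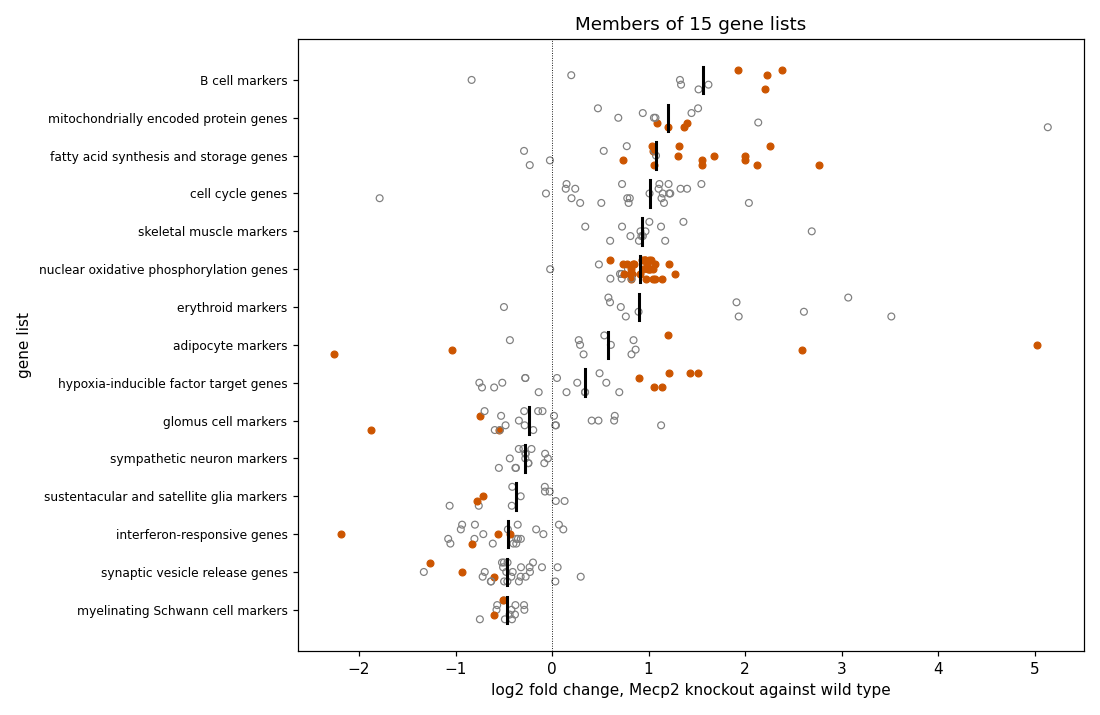
Log2 fold changes (knockout against wild type) of the tested members of the 15 gene lists with a camera adjusted p below 0.06; filled orange points passed the edgeR threshold, open grey points did not, and black bars are list medians. The fatty acid list has a median of 1.08 and the synaptic vesicle list a median of -0.46.

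Other tissues in the dissection varied between libraries. Salivary gland and mucous genes marked the high end of the first principal component (42.1% of variance, exact permutation p = 0.429 for genotype), and the second (23.1%) separated the genotypes (exact permutation p = 0.0286). Centred salivary scores were 2.51 and 3.26 log2 units in wild type replicates 3 and 4 and 1.85 and 0.873 in knockout replicates 2 and 3, against -2.10, -2.15, -2.95 and -1.30 in the other libraries. The salivary list had 1 of 12 members past the threshold, Amy1, which rose (0.56; list adjusted p = 0.313). Skeletal muscle markers had a median log2 fold change of 0.93 with none of 14 past the threshold (camera adjusted p = 0.00226, adjusted p = 0.727 with an estimated correlation), with Myh2 at 2.69 and Myl1 at 1.01. Slc5a5 (-1.10) fell among 7 thyroid markers (list adjusted p = 0.219), whose score stood high in wild type replicate 4. Cartilage and bone markers had no passing member (Ibsp 5.29, Col9a2 0.72, list adjusted p = 0.219). Ibsp stood at 33.7 CPM in knockout replicate 2 and at no more than 0.630 CPM in any other library.

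**Figure D3:**
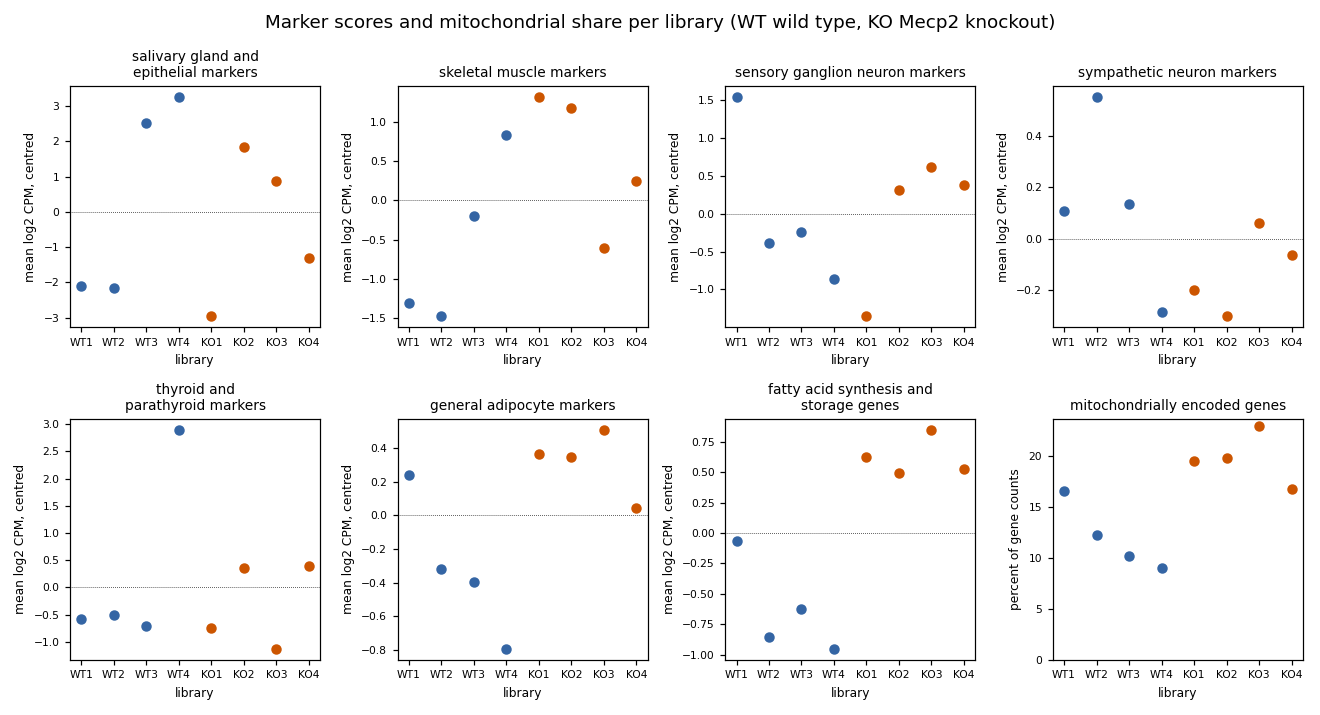
Scores of 7 gene sets (mean log2 CPM of the members, centred on 0) and the percent of gene counts from mitochondrially encoded genes, per library; blue points are wild type (WT) and orange points knockout (KO). The fatty acid score is above 0 in all 4 knockout and below 0 in all 4 wild-type libraries, while the salivary score is high in 2 libraries of each group.

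Camera passed 13 of the 42 lists, 8 higher and 5 lower, but 0 passed with an estimated correlation (3 at an unadjusted p under 0.05). By fry 6 passed, the fatty acid, oxidative phosphorylation, mitochondrially encoded, hypoxia-inducible factor target, erythroid and satellite glia lists. When single libraries were left out, camera lost the satellite glia list without wild type replicates 1 or 2 (adjusted p up to 0.0619), the sympathetic list without wild type replicates 1 or 2 or knockout replicate 2 (up to 0.282), the skeletal muscle list without wild type replicate 1 (0.0515), the erythroid list without wild type replicates 1 or 2 (up to 0.108) and the cell cycle list without wild type replicate 1 or knockout replicate 2 (up to 0.604). It passed the glomus cell and the adipocyte lists in 4 of 8 such fits each. Of the 35 ways to divide the 8 libraries into 4 and 4, 27 gave 13 or more lists, so the number of lists did not stand apart from other divisions.

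Long genes have been reported to rise in brain without MeCP2, and the comparison was made here. Expression of protein-coding genes over 100 kb (2189 genes) relative to shorter ones (12246 genes) was 0.327 ± 0.0876 log2 units (SD, n = 4) in the wild type and 0.296 ± 0.0652 in the knockout. The difference of -0.03 lay within the spread between libraries (exact two-sided permutation p = 0.657).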

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

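List scores were added to the measures examined after the results were seen, and the comparison of read shares was not planned. In each group of 4 libraries, a library was singled out when its gap to the nearest of the others was large against the group's range. Of 354 groups examined, 35 met this, where about 17.7 would by chance, and 14 of the 35 involved wild type replicate 1. None of the values below was tested further except where a later part says so.

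Wild type replicate 1 stood high for Ucp1 (1290 CPM, others 282 to 416), ND5 (9796 CPM, others 5547 to 5889), Epas1 (358 CPM, others 212 to 228), Egln1 (107 CPM), Comt (83.0 CPM), Gja1 (47.7 CPM), Id1 (24.1 CPM), Gm51680 (0.778 CPM), Cd22 (0.973 CPM) and Atp4b (0.0865 CPM, others 0). It stood high for the sensory ganglion genes P2rx3 (50.3 CPM, others 2.16 to 6.27) and P2rx2 (25.3 CPM, others 4.57 to 6.74) and for Bdnf (3.24 CPM), and low for P4ha1 (52.8 CPM, others 84.35 to 89.22). Wild type replicate 2 was high for Bmal1 (7.42 CPM). Wild type replicate 4 was high for Hba-a2 (380 CPM), Stat2 (63.8 CPM) and the thyroid marker score (4.57 log2 CPM, others 0.969 to 1.17).

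Knockout replicate 1 was high for Egr3 (7.77 CPM, others 1.29 to 1.72) and low for the sensory ganglion score (2.93 log2 CPM, others 4.59 to 4.89) and the cholinergic score (4.43 log2 CPM). Knockout replicate 2 was high for Ibsp (33.7 CPM, others 0.240 to 0.630), Retnlg (11.7 CPM), Mmp8 (10.7 CPM) and Bmal1 (9.96 CPM) and low for Me1 (362 CPM, others 430 to 441) and Kcnn3 (29.3 CPM). Knockout replicate 3 was high for Ndufa4 (1033 CPM, others 517 to 541), Uqcrfs1 (837 CPM), Ndufs4 (283 CPM) and the nuclear oxidative phosphorylation score (9.16 log2 CPM, others 8.50 to 8.57). Knockout replicate 4 was high for Gm36860 (2.33 CPM, others 0.509 to 0.601) and low for Epas1 (360 CPM), Kcnk3 (148.5 CPM) and the mitochondrially encoded score (8.57 log2 CPM, others 9.63 to 9.82).

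Outside the gene counts, reads aligned to more than 1 place made up 18.4 ± 1.84% of reads in knockout and 13.5 ± 1.52% in wild-type libraries (exact two-sided permutation p = 0.0286, adjusted over 8 library measures p = 0.0762).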

How the results depend on the processing

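The fits without the 4 libraries highest in salivary transcripts, with a salivary or general adipocyte score in the model, and without the mitochondrially encoded genes were chosen after seeing the data; the others were planned. The count of 1427 genes (969 higher, 458 lower) stayed within 1.5 times of itself under other scalings, filters, 1 surrogate variable, the salivary score and without the mitochondrially encoded genes (1213 to 2021), though with the surrogate variable 766 were lower. It was 2590 (1501 higher, 1089 lower) with DESeq2, 2611 (1537, 1074) with limma-voom, 2532 (1577, 955) at an adjusted p of 0.10 and 434 (322, 112) with a fold change threshold. Leaving out single libraries gave 97 (50 higher, 47 lower, without wild type replicate 3) to 1681 genes (without wild type replicate 1), with 50 to 1162 higher and 47 to 807 lower, the last without wild type replicate 4. Without the 4 salivary-rich libraries, 154 genes passed (107, 47), of which 58 were among the 1427, from 2 libraries per group, and with the adipocyte score 3 passed (1, 2; 2386 at an unadjusted p under 0.05). Mecp2 was then at -3.688 (adjusted p = 0.0502) and -3.645 (adjusted p = 0.0802), past the threshold in the other 18 of 20 settings, and leaving out single libraries gave -4.471 to -3.713. The fits that leave out libraries hold fewer samples, and for the other settings the cause was not tested.

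Same-numbered libraries of the 2 genotypes deviated with correlations of 0.26, -0.57, 0.0729 and -0.336, so nothing in the values shows that the numbers pair the samples. With the replicate number as a replicate block, 172 genes passed (140 higher, 32 lower) and 16 lists.

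The count of 13 lists was 21 without a filter, 0 with an estimated correlation, 6 by fry, 23 without the 4 salivary-rich libraries and 21 with the adipocyte score, and 11 to 20 when single libraries were left out (20 without knockout replicate 3). The inflammatory list turned higher without the 4 salivary-rich libraries (0.6465, adjusted p = 0.01068). Signs also turned for genes that passed in no such fit. Without the salivary-rich libraries these were Kcnk9 (-0.3579), P2rx2 (-0.8836), P2rx3 (-1.546) and Bdnf (-0.2815), and with the adipocyte score Kcnk9 (-0.0954), P2rx2 (-0.7064), P2rx3 (-1.199), Bdnf (-0.9082) and Irak1 (0.01479). Leaving out single libraries gave -0.3426 to 0.08149 for Chga, -0.2058 to 1.948 for P2rx3 and -0.261 to 0.884 for Bdnf. The length difference stayed between -0.0743 and -0.00478 over 15 settings, none past the threshold. At this depth and number of libraries the simulation, with 200 genes changed, recovered 10% of 1.5-fold changes. The data gave 1427 calls, so recovery in the data can differ from that in the simulation. A smaller change that was not called is not shown to be absent.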

Other observations

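Some genes, chosen after their values were seen, give detail to the lipid result. Fasn, Scd1, Scd2 and Srebf1 are members of the fatty acid list and already in its counts. Fasn, the fatty acid synthase, went from 1420 ± 960 to 9647 ± 2018 CPM (log2 fold change 2.76, SE 0.43, edgeR adjusted p = 0.0103), and Scd1, the stearoyl-CoA desaturase, from 5940 ± 3443 to 28304 ± 1883 CPM. Dio2, the deiodinase that activates thyroid hormone in brown fat, rose (2.32, SE 0.43), as did Ppargc1a, a coactivator of mitochondrial genes (1.02, SE 0.22). Scd2 (-0.23) and Srebf1 (-0.29) did not pass (adjusted p = 0.473 and 0.390). Of the 40 tested genes nearest to Mecp2 in gene order, 6 passed, and they are named after their values were seen. Those that rose were G6pdx (1.22, SE 0.13), Idh3g (1.07, SE 0.20), Fundc2 (0.58, SE 0.14) and Opn1mw, next to Mecp2 on the side opposite Irak1 (2.86, SE 0.55), the last from 0.112 to 0.844 CPM. Plxna3 (-0.73, SE 0.12) and Plxnb3 (-0.60, SE 0.14) fell.

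The tests below against general adipocyte markers, the scaling, sympathetic markers and dilution, and the count of divisions, were chosen after the results were seen, and those against brown fat and muscle before the values they measure were seen. Once the results were seen, a demand that markers reach 5 CPM was added to the brown fat test, and an undecided outcome to the dilution test. For the count of genes, chance division of the libraries can be excluded at the 0.05 level. The real division gave 1427 genes, the highest of the other 34 gave 0, and 1 of 35 divisions reached the real count. For the count of lists it cannot, since 27 of 35 divisions gave as many as the real 13 and the highest of the others gave 24.

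For the higher fatty acid genes, more adipose tissue of an unchanged kind as the whole cause is argued against. The list rose above 8 general adipocyte markers, none of them in the list, by 0.615 log2 units with no overlap between groups (exact two-sided permutation p = 0.02857, the smallest possible). That comparison does not cover more fat of another kind. Part of the rise can be adipose tissue, as the 8 markers had a median log2 fold change of 0.57. Of these only Fabp4 passed the threshold, going from 2149 to 4921 CPM, while Adipoq was at 0.33 (edgeR adjusted p = 0.358). With the marker score in the model the list median went from 1.08 (median SE 0.260) to 0.63 (median SE 0.257). Nearly all gene calls then ended, that of Mecp2 among them at -3.98 (SE 0.44) before and -3.65 (SE 0.50) after. Some lost calls kept their fold change with a larger SE, as Chgb at -1.88 (SE 0.23) before and -1.95 (SE 0.33) after. Cfd did likewise, at -2.26 (SE 0.23) and -2.29 (SE 0.31), while others shrank, as Ucp1 from 2.59 (SE 0.51) to 1.67 (SE 0.38). A lost call is thus not in itself a smaller change, and why the calls ended was not tested. The lowest list median over 4 scalings was 1.044, while the median of all genes shifted to -0.03 at most. This argues against the choice among these scalings as the cause. All 4 take most genes as unchanged, so a shift shared by most genes was not tested. TMM factors averaged 1.08 ± 0.055 in the wild type and 0.928 ± 0.071 in the knockout (exact two-sided permutation p = 0.0286, adjusted over 8 library measures p = 0.0762). Against a larger brown share of the fat, the list score rose above that of the brown identity genes by 0.371, which met the bound set beforehand (exact permutation p = 0.02857). However, 3 of those 5 genes averaged under 5 CPM. The others were Ebf2 at 0.26 (SE 0.18, adjusted p = 0.406) and Cox8b at 1.02 (SE 0.31, adjusted p = 0.0713). The median log2 fold change of the 5 was 1.02, near the 1.08 of the list, and Ucp1, outside these 5, was at 2.59. That bound is therefore not used. The brown share stays open, as does an untested effect of genotype on fat cells.

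For the higher nuclear oxidative phosphorylation genes, more muscle as the whole cause is argued against, since with the muscle score in the model the median log2 fold change was 1.137, against 0.92 without it, and 38 of 39 genes were higher. More adipose tissue cannot be told apart from a change within cells, as the list's rise above the general adipocyte markers, 0.232 log2 units, overlapped between groups (exact permutation p = 0.1429), and the list median was 0.44 with their score in the model. An effect of genotype is untested.

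For the lower synaptic vesicle release genes, less ganglion tissue and dilution by other tissue both stay open. The list lay below the sympathetic neuron markers by a further 0.156 log2 units in the knockout (exact permutation p = 0.08571). With the general adipocyte score in the model its median went from -0.46 (median SE 0.193) to -0.62 (median SE 0.271). Dilution by adipose tissue alone would shrink the fall, which did not happen, but the change was smaller than the median SE. Nearly all gene calls ended in that fit, so adipose tissue is not excluded, and other tissues were not covered. Of 28 members, 10 were lower relative to the marker score in every knockout library than in any wild-type library, where chance gives 1.43% of genes. The same held for 1 of the 15 sympathetic neuron markers, Ntrk1. For the 28 members, the other 69 assignments of the libraries gave at most 3 (exact one-sided permutation p = 0.0143, the smallest possible). This counts against a fall alike in every ganglion gene, but of these 10 Syt7 lay farthest below the marker median (-0.9882), short of the 1 log2 unit set for the test, and whether the markers are also made by other tissue in the dissection was not measured. An effect of genotype is untested.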
